A study of Arabidopsis thaliana with 6 samples.

How the data were processed

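RNA of whole seedlings was hybridised to 6 Affymetrix ATH1 arrays, 1 for each of EST and mock at 2 h and 2 for each at 5 h. Hybridisation and scanning were done by an array service provider, per the labels' protocols. The values used were log2 expression per probe set, as deposited by the authors. Per the submitters' processing notes, GCRMA and RMA were used, and their versions, order and settings were not given in the sources used here. GCRMA corrects each probe for background predicted from its base content, so that dim probe sets pile up at a floor, and differences measured against that floor depend on the background model. The labels give different strengths for the ethanol of the mock treatment, so none is printed. A genome build was not given in the sources used here, and no coordinates are printed.

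The lowest log2 value was 2.125 on the 2 h arrays and the 5 h replicate 1 arrays and 2.093 on the 5 h replicate 2 arrays, so the deposited values appear to come from 2 separate normalizations, called normalization sets here. The share of probe sets within 0.001 of the lowest value was 20.9 to 21.4% in the first set and 16.3 to 16.5% in the second. The first principal component (73.2% of the variance) separated the sets. The root mean square difference between arrays was 0.258 to 0.329 (log2) within a set and 0.603 to 0.663 across sets. Over the 12860 probe sets tested, arrays of the same set shared exactly equal values at 2.57 to 7.71% of them and arrays of different sets at 0%, so no array was counted as a copy of another. Each set held EST and mock arrays at 5 h, so the set was used as a block and each pair of arrays was also compared within its set. Same-numbered 5 h arrays deviated together from their group means (r = 0.851 across probe sets). With 2 pairs this is a property of the data, and the labels do not say what a replicate number shares. The 3′ minus 5′ signal of actin was 1.13 to 1.46 and that of GAPDH 0.21 to 0.70 (log2) over the 6 arrays.

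Of the 22810 probe sets, 64 controls were left out. A gene table for the array named 1 gene for 13513 of the remaining 22746, several for 503 and none for 8730. Of the single-gene probe sets, 13436 were matched by gene ID to the TAIR10.1 gene table, which was used for names only. A gene was named only from a probe set with 1 gene. Probe sets with a log2 value of at least 5 on at least 2 of the 6 arrays were tested, 12860 in all and 6817 of them with 1 gene. For a gene with several probe sets the one with the highest mean over the 6 arrays stood for it in the lists.

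Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block in the main design, on the 4 arrays at 5 h, on all 6 arrays with time as an additive term, and as an interaction contrast of the 4 groups. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 6 lists. Fry, which asks whether the members move on balance one way, was an alternative. At 2 h and for mock over time probe sets with a log2 difference of at least 1 were counted, without a test, and at 2 h a fit of the 4 groups with pooled spread was an alternative. Medians of lists at 2 h were ranked among 10000 random lists matched on mean expression in 10 bins.

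The tests, the lists, the rule for named genes and the alternatives, except those named as added later, were fixed before the data were examined. The rule took, at 5 h, up to 12 single-gene probe sets in each direction past the threshold or, where under 5 passed, with a log2 difference of at least 1 in all 4 EST and mock combinations. It took the 8 highest and 8 lowest at 2 h, those with such a difference at both times, and up to 4 members of each list. Up to 2 unnamed probe sets in each direction were added. The alternatives were quantile normalization, median centring, no expression filter or a filter at 7, trended and robust variances, the block, leaving out each array, other thresholds, camera with an estimated correlation and fry. The tests were tried on simulated data with 200 of 12860 genes changed in each of 10 rounds. The share recovered at 5 h was 0% for log2 changes of 1 and 2, 64.0% for 3 and 86.0% for 4, and with the replicate block 0, 28.1, 80.2 and 89.6%. Camera called 100% of lists shifted by 0.5 and 8% of unshifted lists. The simulated genes varied independently, so these rates do not carry over to lists whose members move together. The result of 1 gene family is not reported here. No estradiol-treated arrays without the RD26 construct were analysed here.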

Results

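Transcript levels were measured on Affymetrix ATH1 arrays in whole Arabidopsis thaliana seedlings (Col-0) of an RD26-IOE line, in which estradiol switches on the transcription factor gene RD26. The line was given 10 µM β-estradiol (EST) or ethanol alone (mock) in liquid medium with shaking. The stated purpose was to find genes that respond quickly to raised RD26, a NAC-family factor linked to drought, abscisic acid (ABA) and leaf senescence. There were 6 arrays: 1 EST and 1 mock array at 2 h, and 2 EST and 2 mock arrays at 5 h, which the labels call biological replicates. The table held 22810 probe sets with log2 values. The array medians were 5.57 (EST, 2 h), 5.62 (mock, 2 h), 5.58 and 5.59 (EST and mock, 5 h replicate 1) and 5.82 and 5.82 (EST and mock, 5 h replicate 2). The number of arrays limits the precision of every value below.

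RD26 itself had no probe set named in the gene table used here, so its level is not reported by name. The probe set with the largest EST effect, 253872_at, had no gene listed, so whether it reports on the induced gene itself or on a gene responding to it is not known here. It read 12.61 on the EST array and 9.56 on the mock array at 2 h. At 5 h its mean was 13.37 ± 0.06 (SD, n = 2) with EST and 9.25 ± 0.16 (SD, n = 2) with mock, a log2 difference of 4.12 ± 0.23 (SE). It was higher with EST in each of the 3 pairs of arrays, by 3.05 at 2 h and by 3.96 and 4.27 at 5 h (log2). Its limma adjusted p was 0.155 at 5 h, 0.487 with the replicate as a block, 0.0306 with a trended and robust variance estimate, and 0.157 with that estimate and the block together.

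At 5 h, the time with replicates, the question was which genes differed between EST and mock seedlings. Among probe sets of a named gene, 9 were higher with EST by at least 1 (log2) in all 4 combinations of an EST and a mock array, and 3 were lower. None of them passed the test, so they are described by their values. The largest difference was that of AT3G13672, whose mean was 6.67 ± 0.27 (SD, n = 2) with EST against 2.95 on each mock array. The mock values of this probe set were equal to 2 decimals on all 3 mock arrays, as for a probe set at its own background, so its differences at 2 h and 5 h are read as lower bounds. Its limma adjusted p was 0.183, to which the mock arrays added almost no spread. Next came AT3G05400, of the sugar transporter family, at 7.35 ± 0.26 against 4.48 ± 0.86 (SD, n = 2 each). The serine carboxypeptidase-like gene AT5G22860 was at 8.21 ± 0.28 against 5.99 ± 0.60, and SAG29, also called SWEET15 and encoding a sucrose transporter of senescing leaves, at 7.18 ± 1.03 against 5.01 ± 0.48. The glycosyltransferase gene UGT76E12 was higher by 2.30 and 1.62 in the pairs of replicates 1 and 2, and AT1G29195 by 2.14 and 1.84. For AT2G40435 these differences were 1.24 and 2.83, for the kinase gene AT4G32250 they were 1.46 and 1.68, and for AT2G25625, which encodes the chloroplast-degrading factor CV, they were 1.20 and 1.26.

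On the lower side at 5 h stood XTH26, a cell wall xyloglucan enzyme of root hairs, at 6.78 ± 0.18 with EST against 8.07 ± 0.08 with mock (SD, n = 2 each). The peroxidase gene AT1G34510 was at 7.23 ± 0.68 against 9.01 ± 0.18, and AT5G24313 at 3.36 ± 0.79 against 5.49 ± 0.45. Of the probe sets with no gene listed, 254189_at was higher with EST by 3.51, and 254534_at and 247536_at were lower, with log2 differences of -2.19 and -1.46.

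Over the 12860 probe sets tested at 5 h, limma called 0 at an adjusted p under 0.05, and 141 had an unadjusted p under 0.05 (81 higher and 60 lower). With the replicate as a block, which is also the normalization set described with the processing, it called 0 and 877 had an unadjusted p under 0.05 (394 higher and 483 lower). With no effect, a share of 0.05 of the 12860 would be expected under that p. The 141 fall below that share and the 877 lie above it. With no test, 23 probe sets were higher and 10 lower by at least 1 in all 4 combinations. By the same rule, splitting the 4 arrays by normalization set gave 134 and 495. The pair of replicate 1 alone gave 87 higher and 36 lower, that of replicate 2 gave 52 and 66, and 34 and 19 met the size in both pairs. Leaving out 1 array changed the calls: 28 without EST replicate 1, 22 without mock replicate 1, 12 without EST replicate 2 and 33 without mock replicate 2, in fits that set a lone array of one set against arrays of both. Of the named genes 9 passed in at least 1 of these fits, AT3G13672 and AT3G05400 in all 4. In simulated data the 5 h test recovered 0% of genes changed by 2 (log2) and 64.0% of those changed by 3, so a count of 0 does not speak to changes of 2 or less.

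**Figure D1:**
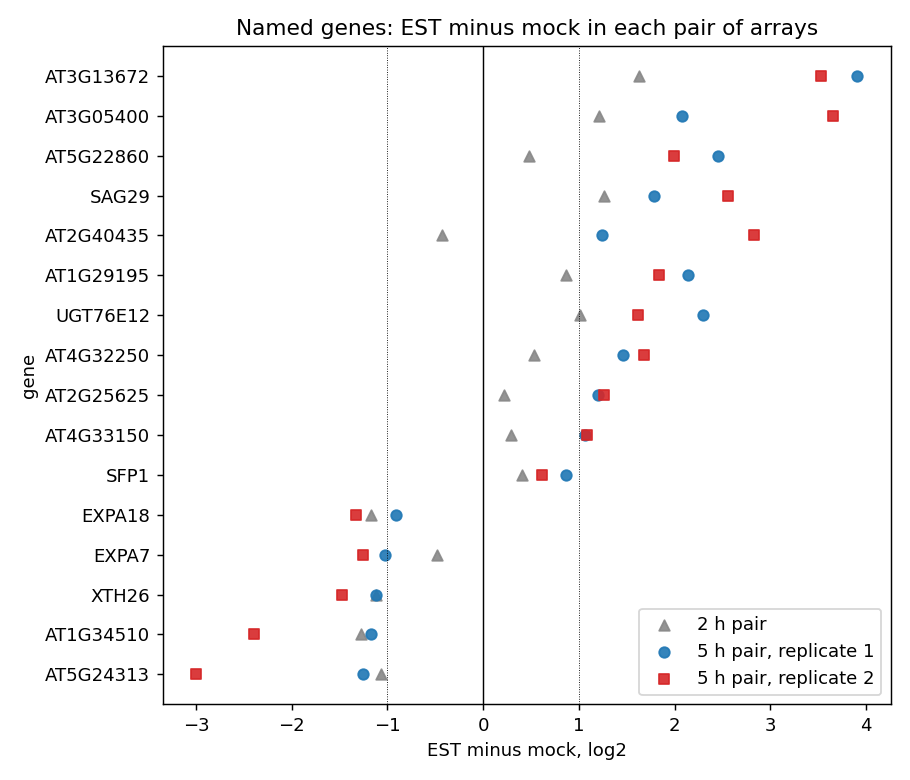
EST minus mock difference (log2, horizontal axis) of 16 named genes (vertical axis) in each pair of arrays, with triangles for the 2 h pair, circles for 5 h replicate 1 and squares for 5 h replicate 2. Dotted lines mark a difference of 1 either way, and AT2G40435 is the gene whose 2 h value (-0.43) has the opposite sign to its 5 h values.

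Among the gene lists fixed before the data were examined, the senescence and dark-induced list (5 of 18 members measured) was higher with EST at 5 h as a set. Its camera adjusted p was 1.07e-08 over 6 lists with the preset correlation of 0.01, and the adjusted p was 0.184 with an estimated correlation. With the replicate as a block the camera adjusted p was 0.000225, and the fry adjusted p was 0.428. The median difference of its members was 0.408 and 3 of 5 were higher in both pairs. No member passed over all genes tested, and 2 passed when adjusted over the list alone, SAG29 and AT2G25625. AT2G25625 is also in the list linked to RD26 in earlier work, which may hold genes picked from these arrays, so its part in the senescence list is not independent evidence. The other members named by rule, SAG101, a lipase-like defence and senescence gene, and the transcription factor gene WRKY6, differed by 0.41 ± 0.26 and 0.32 ± 0.27 (SE). The remaining member, the transcription factor gene WRKY53, differed by 0.27 and -0.55 in the pairs of replicates 1 and 2 and by -0.48 at 2 h.

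The amino acid catabolism list (12 members tested) did not pass, with a camera adjusted p of 0.0573 (upwards), and the adjusted p was 0.397 with an estimated correlation. Its fry adjusted p was 0.0436. The median of its members was 0.17 and 0 in the pairs of replicates 1 and 2, with 8 and 5 of 12 higher. The camera adjusted p was 0.0175 without mock replicate 1 and 0.0195 without EST replicate 2 (upwards), and 0.985 without mock replicate 2, with the direction turned. AT4G33150, the bifunctional lysine degradation gene LKR/SDH, was at 8.86 ± 0.09 with EST and 7.80 ± 0.11 with mock at 5 h (SD, n = 2 each). IVD, an enzyme of leucine breakdown, differed by 0.40 and 1.23 in the pairs of replicates 1 and 2, MCCA, a carboxylase subunit of the same pathway, by -0.76 and -0.46, and ETFALPHA, an electron carrier of branched-chain amino acid oxidation, by 0.32 and 0.11. AT4G33150 and AT2G25625 were the measured members of the list linked to RD26 in earlier work, and 2 of 2 passed when adjusted over the list alone against 0 over all genes tested. That list may hold genes that the study picked from these arrays, so its direction, and that of AT4G33150 in the amino acid list, is not independent evidence. SFP1, a senescence-associated sugar transporter gene and the measured member of the raffinose, trehalose and starch list, was at 10.81 ± 0.14 against 10.08 ± 0.32 (SD, n = 2 each). It did not pass over all genes tested, and as the list had 1 tested member its value adjusted over the list alone is the unadjusted limma p of 0.0406.

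Of the root markers, 2 of 10 were measured, the root hair expansin genes EXPA7 and EXPA18. At 5 h EXPA7 was lower with EST in both pairs (-1.03 and -1.25), and so was EXPA18 (-0.91 and -1.33), with mean log2 differences of -1.14 ± 0.31 and -1.12 ± 0.29 (SE). In the 2 h pair they differed by -0.48 and -1.17. Adjusted over the list alone, 2 of 2 passed, and 0 did over all genes tested. These lower root markers stood in the same arrays as the higher senescence genes.

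**Figure D2:**
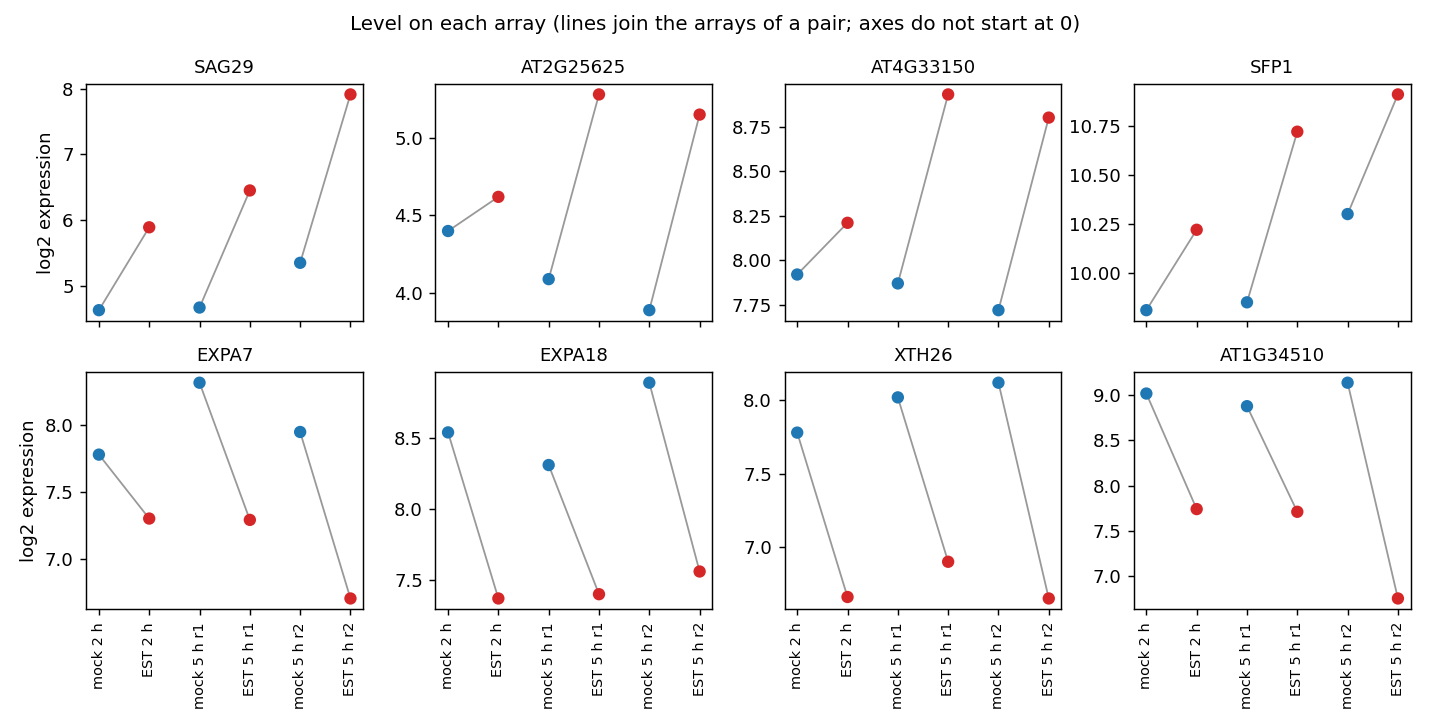
Log2 expression (vertical axes, which do not start at 0) of 8 genes on each of the 6 arrays (horizontal axes), with blue for mock, red for EST and a line joining the arrays of a pair. The 4 genes in the upper row are higher and the 4 in the lower row lower with EST in each of the 3 pairs, as for SFP1 (differences 0.41, 0.87 and 0.61) and XTH26 (-1.12, -1.12 and -1.47).

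The other lists did not pass at 5 h. The ABA and drought response list (3 members tested) had a camera adjusted p of 0.244, and LTI30, COR15B and COR47, which encode dehydrins and a cold-induced chloroplast protein, differed by 0.15, 0.15 and -0.05. Photosynthesis (5 members) had 0.0869, downwards, with LHCB4.2 of the light-harvesting antenna at -0.34 and RCA, the activase of Rubisco, at -0.13. Xenobiotic detoxification (5 members), the list for responses to foreign compounds, had 0.0869, upwards, and 0.00999 with the replicate as a block. The estimated correlation gave an adjusted p of 0.532 for that list without the block. Without mock replicate 1 or EST replicate 2 it passed (6.49e-05 and 7.33e-05), and without EST replicate 1 or mock replicate 2 its direction turned (0.50 and 0.303). Its glycosyltransferase gene UGT73B4 differed by 0.39 and its glutathione transferase gene GSTU22 by 0.28. Autophagy and vacuolar proteolysis (10 members) had 0.0876, downwards, with ATG8H at -0.39 and the vacuolar protease gene GAMMA-VPE at -0.16. Its members other than GAMMA-VPE are ATG8 genes.

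Smaller lists were not tested as sets. NOL, of chlorophyll b breakdown, differed by -0.05, the wall enzyme genes XTH19 and XTH18 of the brassinosteroid and growth list by -0.12 and 0.06, the clock gene GI by -0.20, the zinc-finger gene STZ of the touch and wounding list by 0.05 and AIM1 of peroxisomal beta-oxidation by 0.02. The lists for NAC factors (16 members), salicylate and pathogen defence (14), jasmonate (20), heat shock (8) and low oxygen (9) had no named probe set that passed the expression filter, and their genes were not analysed here.

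At 2 h, with 1 array per group, the differences had no replicate check and are given as values. A limma fit of all 4 groups, in which the 2 h arrays are assumed to vary like those at 5 h, called 0 probe sets at 2 h, with 39 at an unadjusted p under 0.05. EST was higher by at least 1 (log2) for 26 probe sets and lower for 52. The highest named genes were AT3G13672 (1.63), AT5G48430 (1.57), the plastid ATP synthase gene atpH (1.27), SAG29 (1.26) and AT3G05400 (1.21), followed by the plastid genes psbK (1.19) and rpoC2 (1.17) and by AT5G14580 (1.19). The lowest were AT1G76960 (-1.66), AT3G57930 (-1.45), AT1G76270 (-1.40), AT5G38700 (-1.38), AT1G33700 (-1.33), AT1G72920 (-1.28), AT1G34510 (-1.28) and AT2G34910 (-1.27). At 5 h atpH differed by -0.65 and -0.45 and AT5G48430 by 0.08 and -0.01, while AT5G38700 differed by -1.09 and -0.81. Of the gene lists, the 10 autophagy members tested were lower with EST at 2 h. Their median of -0.299 lay at percentile 0 of 10000 random lists matched on expression. All but GAMMA-VPE are ATG8 genes, so this rests on 1 gene family, while the random lists hold unrelated genes. The xenobiotic list had a median of 0.295 (percentile 99.6) and the senescence list one of 0.209 (percentile 98.0). Amino acid catabolism had a median of -0.156 (percentile 3.5), with 8 of 12 members lower, against its upward direction at 5 h. The ABA list had one of 0.027 (percentile 72.6) and photosynthesis one of -0.037 (percentile 45.9). These values are a description of 2 arrays.

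Setting the times side by side asked which differences at 5 h were already seen at 2 h. Named genes with a difference of at least 1 at 2 h and in all 4 combinations at 5 h were AT3G13672, AT3G05400, SAG29 and UGT76E12 on the higher side and AT5G24313, AT1G34510 and XTH26 on the lower side. Among all probe sets, 9 higher and 9 lower met the size at 2 h and in both pairs at 5 h, against 0.069 and 0.077 for independent lists. Of the 34 higher in both pairs at 5 h, 27 were also higher at 2 h (79.4%), and 19 of the 19 lower ones were lower. No array is shared between the times. Across all 12860 probe sets, which are not independent replicates, the 2 h difference and the mean 5 h difference had a Pearson r of 0.171 and a Spearman rho of -0.015. With the 5 h pair of replicate 1 alone r was 0.048 and rho -0.106, and with that of replicate 2 they were 0.246 and 0.126. The 5 h pairs of replicates 1 and 2 had an r of 0.388 and a rho of 0.141.

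**Figure D3:**
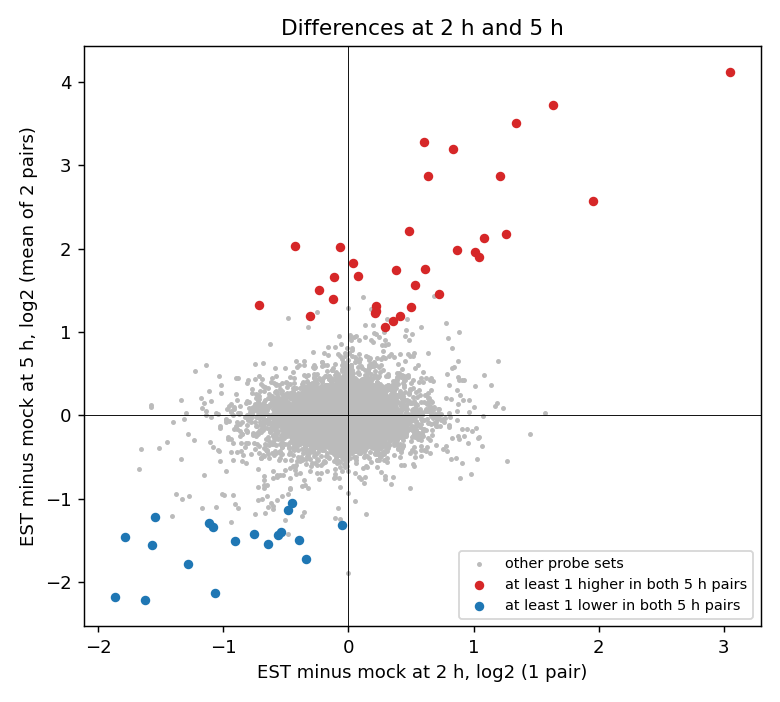
EST minus mock difference at 5 h (mean of 2 pairs, log2, vertical axis) against that at 2 h (1 pair, log2, horizontal axis) for 12860 probe sets. Red and blue points are the 34 higher and 19 lower by at least 1 in both 5 h pairs, of which 27 and 19 have the same sign at 2 h.

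A fit over both times, with 3 EST and 3 mock arrays, assumed the same EST effect at 2 h and 5 h. XTH26 had a log2 difference of -1.24 with a limma adjusted p of 0.401. The fit called 0 probe sets, with 191 at an unadjusted p under 0.05 (90 higher and 101 lower) and a lowest adjusted p of 0.103. With each pair as a block it called 0, with 829 at an unadjusted p under 0.05 (292 higher and 537 lower). In simulated data with 1 effect at both times this fit recovered 72.9% of genes changed by 2 (log2), and with the block 55.9% of those changed by 1 and 88.5% of those changed by 2. The trended and robust estimate called 1, the unnamed 253872_at, at an adjusted p of 0.0284. On all 6 arrays with each pair as a block, camera passed the senescence list (adjusted p 0.0036, upwards), the xenobiotic list (0.0133, upwards) and the autophagy list (0.0036, downwards). With an estimated correlation the adjusted p was 0.362 for each of these lists.

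The difference of the EST effects, 5 h minus 2 h, was tested with the single 2 h arrays assumed to vary like those at 5 h. AT2G40435 went from -0.43 at 2 h to 1.24 and 2.83 at 5 h, and atpH from 1.27 to -0.65 and -0.45, and neither passed. No probe set was called by limma (0), 30 had an unadjusted p under 0.05, and with the normalization set as a block 0 were called and 780 had one. In simulated data this test recovered 0% of genes changed by 4 (log2), so it cannot show that the effects were alike.

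Mock seedlings at 5 h and at 2 h give the change with time in the medium, without a test. GI, the clock gene measured, read 7.77 at 2 h and 7.85 ± 0.38 (SD, n = 2) at 5 h. That mean joins 8.12 on mock replicate 1, of the normalization set of the 2 h arrays, and 7.58 on mock replicate 2, of the other set. Both mock arrays at 5 h were higher than the 2 h mock array by at least 1 (log2) for 33 probe sets and lower for 22. With replicate 1 alone, the array of the same normalization set as the 2 h arrays, the counts were 78 and 133. Mock replicate 2 against mock replicate 1, which crosses the sets at 5 h, gave 918 and 257.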

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

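The groups of genes named here were set up after the data had been seen. They were singled out because their median EST minus mock difference at 2 h had the opposite sign to that in both pairs at 5 h, a difference between the times that was not tested and that rests on 1 array per group at 2 h. Over 38 plastid-encoded probe sets the median was 0.46 at 2 h, with 31 of 38 higher, and -0.055 and -0.003 at 5 h. Over 7 mitochondria-encoded probe sets it was 0.536 at 2 h and -0.029 and -0.299 at 5 h. Of 33 gene families and organelle groups 10 met this condition. Among these the 2 h medians were also 0.257 for rps, 0.272 for GH, 0.177 for EXPA, 0.151 for TRM, 0.022 for ALDH, 0.001 for RALFL and -0.022 for CML. Signs of medians can differ in this way by chance, so the count is not evidence of a change with time. The families share the start of their symbols, so GH joins GH3 and GH9 genes. The rps probe sets are not part of the 38, but their probe set numbers lie between those of plastid-encoded ones, so they are not separate evidence. Genes of root tissue other than root hairs (25 probe sets) met the condition too, with a median of 0.03 at 2 h and -0.088 and -0.018 at 5 h.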

How the results depend on the processing

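The fold counts within sets, the block of the normalization set in the interaction, the camera fit on all 6 arrays, the correlations with 1 pair at 5 h alone and the mock comparison with replicate 1 alone were added after the data were seen. With the replicate block the 5 h fit and the fit over both times called 0, as without it, and so did the interaction. The counts over both times and of the interaction were also 0 when any 1 array at 5 h was left out. Calls at 5 h and over both times became 1 and 1 with the filter at 7 and 1 and 1 with trended, robust variances, in each case 253872_at (fewer probe sets were tested with the filter at 7). With trended, robust variances and the replicate block together, a setting added after the data were seen, 0 were called at 5 h. Leaving out 1 array at 5 h gave 12 to 33 calls, and 33 or 53 probe sets differed by at least 1 in all 4 combinations or in both same-set pairs. The counts of 23 higher and 10 lower in all 4 combinations became 13 and 6 with the filter at 7 and 35 to 61 and 21 to 39 without 1 array, which leaves fewer combinations to meet, and 19 were lower in both same-set pairs.

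At 2 h the counts of 26 higher and 52 lower became 14 and 26 with the filter at 7, 1 and 0 at a difference of at least 2, and 0 and 0 in a 4-group fit with pooled spread, in which 39 had an unadjusted p under 0.05. The mock counts over time became 78 and 133 with replicate 1 alone. The number of lists that passed was 1, and became 4 with no filter, 2 with the filter at 7, 0 with an estimated correlation, 2 with the replicate block, 2 with a trended variance in camera, 3 on all 6 arrays with each pair as a block, and 1 to 3 without 1 array. Besides the senescence list, amino acid catabolism passed with no filter (0.0241), the filter at 7 (0.0185) and a trended variance (0.0374), photosynthesis (0.0338) and autophagy (0.0147) with no filter, and the xenobiotic list with the block (0.00999). The senescence list was higher under each alternative run. Its camera adjusted p ran from 1.07e-08 to 0.0296, except 0.184 with an estimated correlation, and its fry adjusted p was 0.428. The 0.0296 came with the filter at 7, which left out SAG29 and AT2G25625, so it rests on SAG101, WRKY6 and WRKY53. Without 1 array, the adjusted p ranged from 0.0175 to 0.985 for amino acid catabolism, 0.182 to 0.891 for the ABA list and 6.49e-05 to 0.50 for the xenobiotic list, each with a changed direction without mock replicate 2 and the xenobiotic list also without EST replicate 1.

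Of 54 named genes, 0 changed direction over 162 values under another normalization or the block. The arrays at 5 h are balanced over the replicates, so the block could not change these log2 differences. When 1 array was left out, 21 did, none of which had a difference of at least 1 in all 4 combinations. Genes with such a difference could not turn, since the combinations left keep its sign. Their log2 differences at 5 h without 1 array ranged from -0.76 to 0.82 for AT5G48430, -1.65 to 0.55 for atpH, -0.13 to 0.42 for AT5G14580, -0.22 to 0.44 for rpoC2, -1.26 to 0.45 for AT1G76960, -0.21 to 0.07 for AT1G76270, -0.91 to 0.46 for AT1G72920, -0.22 to 0.13 for NOL, -0.23 to 0.13 for COR47, -0.52 to 0.16 for PORB, -0.32 to 0.08 for PSAE-1, -0.29 to 0.04 for XTH19, -0.40 to 0.52 for XTH18, -0.47 to 0.07 for GI, -0.10 to 0.87 for UGT73B4, -0.20 to 0.76 for GSTU22, -0.28 to 0.71 for AT2G04050, -0.02 to 0.17 for UGT73B5, -0.16 to 0.25 for STZ, -0.45 to 0.10 for ATG8F and -0.16 to 0.21 for AIM1. In such a fit the arms hold different normalization sets, and the lone array is assumed to vary like the others. Causes of the other changes were not tested. The alternatives for the RD26 level were not run, because no probe set is named for RD26 here. Probe sets of low signal, such as that of AT3G13672 in mock, give differences that depend on the background correction.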

Other observations

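The split of the prediction for chance into a part for 5 h and a part for 2 h, the test of the normalization set and the bootstrap errors of medians were chosen after their results had been seen, and the root lists were written from memory after the genes with the largest differences had been seen. In the group of root hair genes, 14 of the 15 members seen beforehand were lower with EST in each of the 3 pairs, with medians of -0.727 at 2 h and -0.907 and -1.471 at 5 h. They included the peroxidase gene AT4G26010 (-0.69, -0.66 and -1.35) and the cellulase gene GH9C1 (-0.62, -0.62 and -1.48), and the exception was GH9C2 (0.43, -0.10 and -0.02). The 14 include AT3G54580, whose differences of 0.00, -0.92 and -2.86 make it lower at 2 h only beyond the second decimal. In 9 held-out members whose values had not been seen the medians were -0.104, -0.699 and -0.673, with the extensin-like gene AT5G06630 at -0.10, -0.71 and -1.75, HRGP1 at 0.05, -0.72 and -1.33 and AT4G25790 at -0.67, -0.89 and -0.86. Of these 9, 3 were lower in each of the 3 pairs and 1 was higher in each, AT2G47540 (0.17, 0.09 and 0.02). At 2 h 3 of the 9 were higher, and at 5 h 3 and 1 were. AT3G51350, with a low mean level of 4.07, differed by 0, -0.8 and 0. On the 4 arrays at 5 h camera placed the held-out list lower (adjusted p 3.46e-09 over 2 lists), and the adjusted p was 0.0491 with an estimated correlation and 0.000245 with the replicate as a block. On all 6 arrays with each pair as a block the adjusted p was 0.000375, and 0.309 with an estimated correlation. The other root genes did not pass (0.512 at 5 h and 0.534 on all 6 arrays). The camera fits at 5 h alone were added after those on all 6 arrays had been seen. Other root genes (25) had medians of 0.03, -0.088 and -0.018, with the abundant PYK10, of root ER bodies, at -0.07, -0.19 and -0.03 and a mean level of 13.43. AT3G01190 was left out of that list because its value had been seen.

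A hypothesis is that root hair genes respond to the EST treatment at 5 h. A lower share of root tissue in the EST samples would lower other root genes alike. Over the 3 pairs their median lay 0.398 above that of the held-out root hair genes (bootstrap SE 0.225) and their mean 0.425 above (SE 0.127). Over the 2 pairs at 5 h these gaps were 0.409 (bootstrap SE 0.28) and 0.5 (SE 0.164). The errors in this paragraph run over member genes measured on the same arrays, so they hold no spread between samples. The gaps of means exceed 2 of these errors and those of medians do not. Errors of this kind cannot weigh a difference between samples, so the share of root tissue stays open. An effect within 1 normalization set alone would spare the pair of the other set. The higher of the 2 medians at 5 h, 1 per set, was -0.673 (bootstrap SE 0.31). An offset between the sets cancels within each pair, so these medians could not have shown it. At 2 h the median was -0.104 (SE 0.185), a pair that the prediction as first written had included. Chance in picking genes singly is argued against at 5 h. There the held-out medians lay at percentile 0.01 or below of 10000 matched lists. At 2 h it is not, at percentile 15.66, so the prediction as first written for all 3 pairs was not met. The matched lists hold unrelated genes, so they cannot weigh a chance difference between samples that root hair genes share. Estradiol itself and RD26 cannot be told apart, since each EST array had both, and the only indirect value is the xenobiotic list's median of 0.261 over the 3 pairs.

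Of 33 gene families and organelle groups, set up after the data had been seen and tested with camera on all 6 arrays with each pair as a block, plastid-encoded genes passed (adjusted p 0.019, upwards), and the adjusted p was 0.973 with an estimated correlation. On the 4 arrays at 5 h alone they did not pass (adjusted p 0.97, downwards), and their medians there were -0.055 and -0.003 against 0.46 at 2 h. On all 6 arrays the autophagy-related ATG family had a camera adjusted p of 0.129 and the PDF group one of 0.149. The ATG8 genes of the ATG family are also in the autophagy list. Members of the PDF group share the start of their symbols, and PDF1A and PDF1B among them are not defensin genes. At 5 h alone the expansin family EXPA passed (5 probe sets, adjusted p 0.0132, downwards), and the adjusted p was 0.999 with an estimated correlation and 0.315 with the replicate as a block. That family holds EXPA7 and EXPA18.

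The count of 191 probe sets at an unadjusted p under 0.05 over both times was set against the 10 splits of the 6 arrays into 3 and 3. As many were found in 7 of the 10 splits, the real one included, and the highest other count was 3850, in a split that kept 3 arrays of the first normalization set together and put the remaining first-set array with the second set. The 6 other splits with as many each put both arrays of at least 1 pair on the same side, and the 3 other splits that parted each pair gave 14, 42 and 59. With 10 splits a share under 0.05 cannot be reached. Counts several times the real one point to a structure of the arrays. With each pair as a block the real split gave 829, and the other splits were not run with that block. With no effect, a share of 0.05 of the 12860 probe sets tested would be expected under an unadjusted p of 0.05. The 829 lie above that share. Probe sets of the same arrays are not independent, and the blocked count has no other split to be set against. The 829 alone is for these reasons not evidence of an EST effect. At 5 h, splitting the 4 arrays by normalization set called 5265 probe sets.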
